A study of Rattus norvegicus with 14 samples.

How the data were processed

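Left ventricle RNA (5 µg of total RNA per animal, per the labels) of 7 control and 7 diabetic male Wistar rats was measured on Affymetrix Rat Genome 230 2.0 arrays. Groups and replicate numbers came from the sample titles. One label of the diabetic samples names saline, while their titles, their source and the protocol name diabetes and streptozotocin, and the titles were followed. RNA was extracted with 1 of 2 kits, and the labels do not say which animal got which.

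The deposited table holds 1 probe set intensity per probe set and array on a linear scale, for 31099 probe sets. MAS5, RMA, affy and limma are named per the submitters' processing notes, without roles, and their versions are not given in the sources used here. The deposited intensity values are neither on a log2 scale nor equal in distribution between arrays: array medians ran from 14.8 to 85.3. The test plan had assumed log2 values ready for a linear model. The values were therefore scaled here to a trimmed mean of 500 per array (2% trimmed at each end), 50 was added, log2 was taken and the arrays were quantile normalised, as decided before any group difference was computed. Quantile normalisation had been planned as an alternative and so became part of the main setting. Scale factors ran from 1.61 to 8.81. Quantile normalisation assumes that most genes do not change and gives tied values at the top of the range. The 57 Affymetrix control probe sets were left out of the tests.

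Gene symbols came from a table that pairs probe sets with the array's annotation: 20826 probe sets had 1 symbol, 436 had several and 9780 had none. Of those with 1 symbol, 20758 were looked up by gene ID in the RefSeq gene table of the rat assembly GRCr8, and 0 changed. That table was used for names and for the order of neighbouring genes only. No coordinates are printed, since the build behind the array is not given in the sources used here. A gene was represented by its probe set with the highest mean signal. Of 245 called genes 79 had several probe sets. For 16 of these another probe set was called in the same direction, and for 0 in the opposite direction. A further 72 called probe sets had several symbols or none and are not named.

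Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, two-sided), with Benjamini-Hochberg adjustment over 31042 probe sets and a threshold of 0.05. Gene lists (43, with 768 of 847 members measured) were tested with limma's camera at its preset inter-gene correlation of 0.01, with the correlation estimated per list and with fry. All adjusted p values of lists are over the 43 lists. The groups, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. That rule named the 10 largest rises and 10 largest falls among called genes with 1 symbol, a set of key genes of diabetic heart metabolism, contraction and fibrosis, and up to 4 members per list with the smallest p. Genes named outside the rule are said to be so. Array spread was compared by an exact two-sided permutation test over all 3432 assignments. The samples are separate animals per the labels, so limma's p values per probe set and the exact permutation tests over arrays measure the spread between animals. Camera at the preset correlation takes the correlation between genes as fixed. Its p values do not measure how the members of a list vary together between animals.

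Batches were defined from the poly-A spike-in and beta-actin control probe sets, by the largest gap in each, after seeing those probe sets and before any group difference. Between batches 2707 probe sets differed. Deviations from the group mean correlated by 0.172 on average between arrays of the same batch and by -0.0887 between arrays of different batches. Batch was tried as a block, as a block of spike-in classes alone, and by refitting within each batch. Correlations between all 91 pairs of arrays lay between 0.919 and 0.981, so no array repeats another.

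Set beforehand as other settings were array weights, a trended robust variance prior, cyclic loess, subtraction of array medians, replicate number as a block, an RNA quality covariate, each array left out, filters on dim probe sets, other thresholds, an exact rank-sum test, other rules for several probe sets and other list tests. Chosen after seeing the data were the batch settings, offsets of 16 and 200, no scaling, trimmed-mean scaling alone, removal of the 3 dimmest or the 3 most deviating arrays, an atrial marker covariate and the batch block with the trended prior. The steps were tested on simulated data with 200 of 31042 probe sets changed between 7 and 7 arrays: 47.0% of those changed by log2 1 were called and 8.0% of those changed by 0.5. In the brighter part of the probe sets these shares were 77.8% and 13.5%. Of 59 calls 5.08% were unchanged probe sets, 0 were called with no change, and 0 of 43 unshifted lists passed. The simulated noise was independent between probe sets and held no batches. It therefore could not show false list calls from genes that vary together.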

Results

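The data are gene expression profiles of the left ventricle of male Wistar rats. Controls were given saline into the tail vein, and diabetic animals streptozotocin at 60 mg/kg, a compound that destroys the insulin-producing beta cells of the pancreas. Hearts were taken after 16 weeks, and RNA from 7 control and 7 diabetic animals was hybridised to 14 Affymetrix Rat Genome 230 2.0 arrays, 1 animal per array. On this array a gene is measured by 1 or more probe sets, each a group of short DNA probes. The comparison asks how gene expression in the left ventricle differed between diabetic and control rats. Median deposited signal per array ranged from 14.8 (diabetic replicate 1) to 85.3 (diabetic replicate 2), and the number of arrays limits the precision. Fold changes below are on the log2(scaled signal + 50) scale, diabetic over control, and understate the change of genes with low signal. Background could not be judged per probe set, because no detection calls were used here.

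The arrays were sorted into 3 batches by their control probe sets, and each batch held both groups. Batch A held 2 control and 2 diabetic arrays, batch B 2 and 2, and batch C 3 and 3. The poly-A spike-ins, control transcripts added to the RNA, lay between -7.23 and -6.15 (log2 ratio to the cre control) in batch C, and between -5.02 and -4.41 in batches A and B. The beta-actin 3' over 5' log2 ratio was 1.41 to 1.71 in batch A and 0.67 to 0.84 in batch B. Batch C, set by the spike-ins alone, spanned 0.67 to 1.47. Between the groups, this ratio averaged 1.03 ± 0.40 in control and 1.09 ± 0.39 in diabetic (SD, n = 7, exact two-sided permutation p = 0.818).

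**Figure D1:**
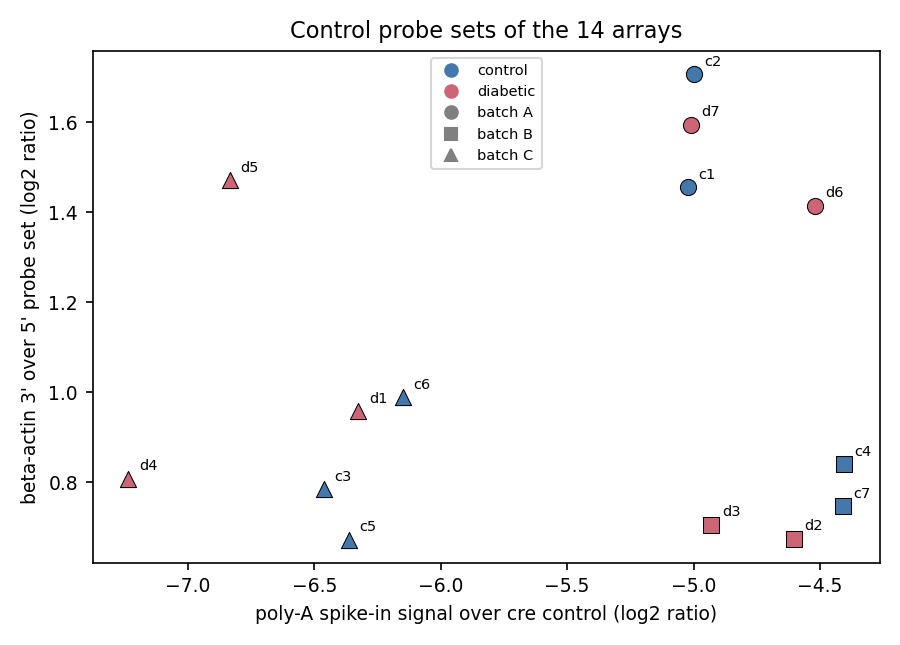
Each point is 1 array, coloured by group and shaped by batch, with the poly-A spike-in log2 ratio on the x axis and the beta-actin 3' over 5' log2 ratio on the y axis; c and d mark control and diabetic replicates. Each of the 3 batches holds arrays of both groups.

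Lists of fatty acid oxidation and lipid handling genes were higher in the diabetic left ventricle, and that of amino acid breakdown was lower. Glucose uptake and glycolysis (5 of 19 members called) and ketone body metabolism (2 of 6) tested lower at the preset correlation, calls lost with an estimated one (adjusted p = 0.0916 and 0.0552 with an estimated correlation). The largest rise was that of Angptl4, a secreted inhibitor of lipoprotein lipase, which was 23.5-fold higher (95% interval 14.6 to 37.9; log2 signal 6.80 ± 0.85 in control and 11.36 ± 0.43 in diabetic, SD, n = 7, limma adjusted p = 1.36e-06). Its control signal lay near the floor set by the offset, so the size of the Angptl4 change depends on it (log2 4.56, against 5.22 with an offset of 16 and 3.36 with 200, both chosen after seeing the data). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 4.27-fold higher (3.39 to 5.39; adjusted p = 2.71e-06). Slc2a4, the insulin-responsive glucose transporter GLUT4, was 4.09-fold lower (log2 signal 12.68 ± 0.28 in control and 10.65 ± 0.35 in diabetic; adjusted p = 6.72e-06). Bdh1, a mitochondrial enzyme of ketone body oxidation, was 5.74-fold lower (10.72 ± 0.49 and 8.20 ± 0.70; adjusted p = 0.000166). For each of these 4 genes all 7 diabetic animals lay beyond all 7 controls.

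Of 31042 probe sets tested, 354 differed (192 higher and 162 lower in diabetic, limma adjusted p under 0.05), and 306 of them differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 2981, against 1552 by chance. Over 14217 named genes, each by its brightest probe set, 134 were higher and 111 lower. Groups did not overlap in 373 probe sets, 1.20% of those tested, against 0.0583% by chance. With batch as a block, limma called 645 probe sets (326 higher, 319 lower), and 350 of the 354 were among them. Groups are balanced within the batches, so the block leaves every fold as it was. Within batches A, B and C limma called 0 probe sets each, with 2390, 3203 and 2426 at an unadjusted p under 0.05. All 354 had the pooled sign within each batch, though they were chosen on all arrays. Probe sets called from the other batches alone had the same sign in the left-out batch for 168 of 175 (A), 170 of 172 (B) and 202 of 213 (C), against 57.4%, 57.8% and 57.5% of all probe sets. Leaving out the 3 dimmest arrays (control replicates 3 and 5, diabetic replicate 1), a choice made after seeing the data, lowered the count to 189.

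The other large rises included several genes of lipid handling. Acot1, a thioesterase that releases fatty acids from acyl-CoA, was 10.4-fold higher, Gpihbp1, which anchors lipoprotein lipase on capillaries, 5.23-fold, and Ucp3, a mitochondrial carrier of the uncoupling protein family, 3.99-fold (log2 changes 3.38 ± 0.26, 2.39 ± 0.15 and 2.00 ± 0.24, SE). Pik3c2g, a class II phosphoinositide kinase, was 10.1-fold higher, Tceal5 6.70-fold, Bex1 6.69-fold, Rbp7, a retinol-binding protein, 4.41-fold, and Adgra1, an orphan adhesion receptor, 3.70-fold. In all of these, all 7 diabetic animals lay above all controls (limma adjusted p from 1.32e-06 for Bex1 to 0.000518 for Adgra1). The control signals of Acot1, Tceal5 and Adgra1 (log2 6.88, 6.81 and 6.07) lay near the floor set by the offset. The sizes of their changes depend on it. Probes of Acot1 and of its neighbouring copies Acot2, Acot3 and Acot4 can bind related transcripts, so their separate values are uncertain.

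The largest fall was that of Card9, an adaptor of innate immune signalling, by log2 -3.46 ± 0.24 (SE, log2 signal 10.17 ± 0.27 in control and 6.71 ± 0.62 in diabetic, SD, n = 7, limma adjusted p = 1.32e-06). The diabetic signal of Card9 lay near the floor set by the offset, so the size of its change depends on it. Sctr, the secretin receptor, was 3.42-fold lower, Fxyd3, a regulator of the sodium pump, 3.24-fold, Dcxr, a carbonyl reductase, 3.24-fold, and Ckb, the brain-type creatine kinase, 3.13-fold. Adra1d, an alpha-1 adrenergic receptor, was 3.05-fold lower and Hk2, the insulin-responsive hexokinase, 2.98-fold (adjusted p = 0.00132 and 0.000321). The diabetic signals of Sctr and Adra1d (log2 6.71 and 6.56) also lay near the floor, so the sizes of their changes depend on the offset too. Inha, the inhibin alpha subunit, was 2.87-fold lower in 6 of 7 animals beyond all controls (adjusted p = 0.0287). Its call was lost when any of 7 arrays was left out (control replicates 3, 4, 5 and 7, diabetic replicates 1, 3 and 7), with adjusted p up to 0.0674.

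**Figure D2:**
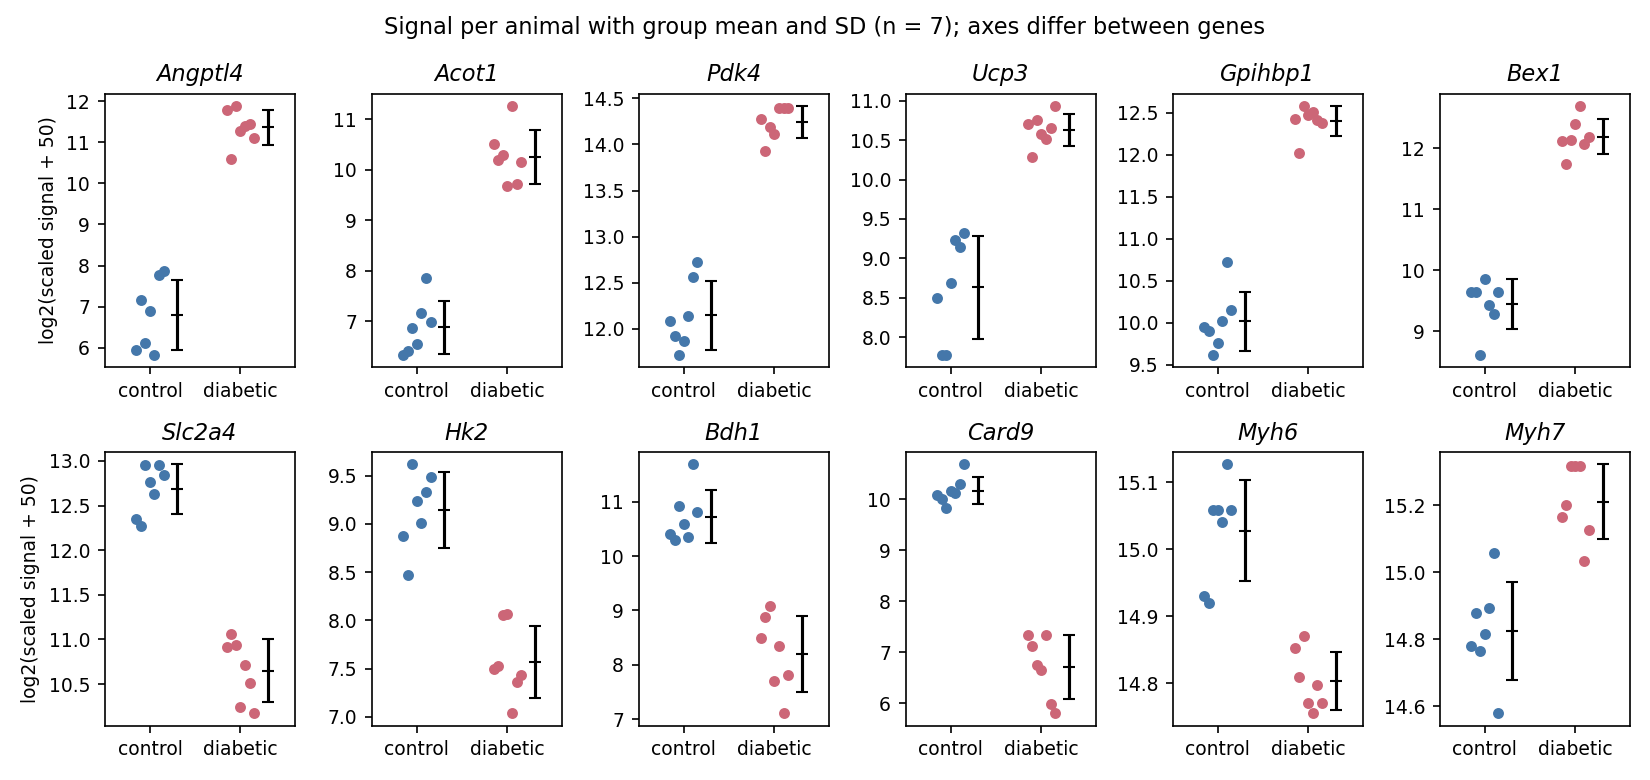
Each panel shows 1 gene, with the log2(scaled signal + 50) of each animal on the y axis, control in blue and diabetic in red; the bar beside the points is the mean with the SD (n = 7). Angptl4 averaged 6.80 in control and 11.36 in diabetic, and Slc2a4 12.68 and 10.65.

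Fatty acid oxidation in mitochondria was the gene list with the smallest p at the preset correlation, and amino acid breakdown with an estimated one. Of its 23 measured members 7 rose and 1 fell (15 and 1 adjusted over the list alone), and the list as a whole was higher (mean log2 change 0.45, camera adjusted p = 3.69e-16; adjusted p = 0.00817 with an estimated correlation). Decr1, which handles unsaturated fatty acids, rose 2.12-fold (log2 1.08 ± 0.10, SE, n = 7 per group), Cpt1a, the acyl transferase that lets long-chain fatty acids enter mitochondria, 2.14-fold, and Eci1, an enoyl-CoA isomerase, 1.68-fold. Cpt1b, the muscle form of that acyl transferase, was not called (log2 0.18 ± 0.11, adjusted p = 0.672). Echs1, a hydratase of the same cycle, fell (log2 -0.51 ± 0.10). The mean shift was 0.55, 0.40 and 0.41 within batches A, B and C. With batch as a block 13 members rose and 1 fell, and without the 3 dimmest arrays 4 rose and 0 fell. Some of the 7 rises were fragile (genes named outside the rule). The calls of Acaa2 and Slc25a20 were each lost for 13 of the 14 arrays left out singly, and that of Eci2 for 12. Their limma adjusted p rose to 0.0998, 0.110 and 0.0850.

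The lists of peroxisomal fatty acid oxidation and of lipid uptake and storage also shifted up. Of 13 peroxisomal members 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 3.28e-07; adjusted p = 0.00817 with an estimated correlation). These were Acot4 (log2 1.69 ± 0.23, SE), Pex11a, a factor of peroxisome division (0.88 ± 0.16), Ech1 (0.60 ± 0.11) and Hsd17b4 (0.51 ± 0.10). Of 17 members of the uptake and storage list 6 rose and 0 fell (10 and 3 adjusted over the list alone, camera adjusted p = 2.57e-10; adjusted p = 0.00817 with an estimated correlation). Beside Angptl4 and Acot1 these included Mgll, monoglyceride lipase (1.07 ± 0.16), and Pnpla2, the triglyceride lipase ATGL (0.95 ± 0.16). Angptl4 inhibits lipoprotein lipase, and Mgll and Pnpla2 are lipases, so the higher list does not show more uptake or storage. The mean change of this list was 0.84 and its median 0.46. Among its 6 rises, G0s2 and Slc27a1 (named outside the rule) each lost their call for 3 of the 14 arrays left out singly. Mean shifts within batches A, B and C were 0.44, 0.36 and 0.51 for the peroxisomal list and 0.92, 0.74 and 0.85 for the other.

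Among markers of fat cells, 3 of 11 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.000105; adjusted p = 0.0304 with an estimated correlation). They were Aqp7, a glycerol channel (log2 1.30 ± 0.14, SE), Cfd, the secreted protease adipsin (1.23 ± 0.16), and Fabp4, a fatty acid binding protein also made by capillary cells (0.61 ± 0.11). Adipoq, Plin1, Cidec and Lep, also markers of fat cells, were not called (log2 0.36, 0.05, 0.15 and -0.06, named after their values were seen). Over single animals the log2 signal ran from 5.85 to 7.76 for Adipoq and from 5.97 to 7.56 for Plin1, reaching near the floor set by the offset. A change in Adipoq or Plin1 could thus have been understated. The list shifted by 0.57, 0.51 and 0.33 within batches A, B and C, and with batch as a block its adjusted p was 0.0707 with an estimated correlation. Without the 3 dimmest arrays 2 of its members rose and 0 fell.

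Breakdown of branched-chain and other amino acids shifted down. Of 20 measured members 0 rose and 8 fell (0 and 10 adjusted over the list alone, camera adjusted p = 2.50e-14; adjusted p = 0.00621 with an estimated correlation). Bcat2, the mitochondrial branched-chain aminotransferase, changed by log2 -1.21 ± 0.14 (SE), Dbt, a subunit of the branched-chain keto acid dehydrogenase, by -1.10 ± 0.14, Ivd, isovaleryl-CoA dehydrogenase, by -1.10 ± 0.15 and Mccc1 by -0.60 ± 0.10. All 7 diabetic animals lay below all controls for these 4 genes. The list shifted by -0.42, -0.41 and -0.48 within batches A, B and C, and 4 members fell without the 3 dimmest arrays. Among the 8 falls, Ppm1k and Bckdhb (named outside the rule) lost their calls for 9 and 6 of the 14 arrays left out singly. Their limma adjusted p rose to 0.0708 and 0.0598.

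Of 19 genes of glucose uptake and glycolysis 0 rose and 5 fell (1 and 7 adjusted over the list alone, camera adjusted p = 4.38e-07; adjusted p = 0.0916 with an estimated correlation). Beside Slc2a4 and Hk2 these included Slc2a1, the basal glucose transporter GLUT1 (log2 -0.99 ± 0.14, SE), and Pfkfb2, which makes an activator of phosphofructokinase (-0.73 ± 0.12). Its mean shift was -0.41, -0.34 and -0.45 within batches A, B and C, and with batch as a block the adjusted p was 0.0120 with an estimated correlation. Of 6 genes of ketone body metabolism 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.00714; adjusted p = 0.0552 with an estimated correlation). Oxct1, the enzyme that activates acetoacetate, changed by log2 -1.03 ± 0.12, beside Bdh1. Within batches the list shifted by -0.66, -0.36 and -0.66.

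In the list of pyruvate dehydrogenase and its regulators, 1 of 12 rose (Pdk4) and 1 fell (Pdp2, a phosphatase that activates the complex, log2 -1.33 ± 0.18, SE), with 1 and 2 adjusted over the list alone. The list tested lower at the preset correlation (camera adjusted p = 0.0204, and 0.141 with an estimated correlation), although Pdk4 opposes the complex. Shifts of the list within batches A, B and C were 0.03, -0.08 and -0.18, and its camera adjusted p was 0.0566 without control replicate 5. Of 34 oxidative phosphorylation genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), Cox7a1, a heart and muscle subunit of cytochrome c oxidase (log2 -1.17 ± 0.12). That list tested lower with a mean change of -0.15 (camera adjusted p = 0.000133; adjusted p = 0.0741 with an estimated correlation; within batches -0.11, -0.13 and -0.18). The citric acid cycle list had 0 of 15 members called either way, also over the list alone (camera adjusted p = 0.0204; adjusted p = 0.105 with an estimated correlation; 0.0574 without diabetic replicate 7). Its lowest p belonged to Idh3b and Sucla2 (both log2 -0.29), and its shifts within batches were -0.09, -0.09 and -0.12. The small shifts of these 3 lists depended on the scaling. With array medians subtracted the calls were lost for pyruvate dehydrogenase (adjusted p = 0.362), oxidative phosphorylation (0.216) and the citric acid cycle (0.808), and with cyclic loess for the citric acid cycle (0.162).

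Contractile and stress genes of the heart had few calls. Of 20 sarcomere genes 0 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.117, 0.0397 with a variance prior that follows the signal level). Tmod1, which caps actin filaments, changed by log2 -0.41 ± 0.09 (SE), a call lost for 12 of the 14 arrays left out singly (limma adjusted p up to 0.103). Myh7, the slow beta-myosin heavy chain, was 1.31-fold higher (95% interval 1.13 to 1.52) and Myh6, the fast alpha form, 0.856-fold (0.753 to 0.973). In the main fit neither passed over all probe sets (adjusted p = 0.0968 and 0.367), whereas adjusted over the 20 key genes measured they had 0.00318 and 0.0335. With batch as a block, chosen after seeing the data, Myh7 passed over all probe sets (limma adjusted p = 0.0424) and Myh6 did not (0.168). With a robust variance prior that also follows the signal level, limma called both (adjusted p = 0.00128 and 0.0148). For Myh6 all 7 diabetic animals lay below all controls (exact permutation p = 0.000583). Nppa, the atrial natriuretic peptide, was not called (log2 0.56 ± 0.18, adjusted p = 0.237), though it passed adjusted over the key genes (0.0137). Also not called were Nppb (-0.26 ± 0.17), Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.04 ± 0.08), and Kcnip2 (0.01 ± 0.11). Myh6, Myh7 and Atp2a2 lie near the top of the signal range, where quantile normalisation gives tied values and saturation, not tested here, would understate a change. Among 15 genes of the fetal and hypertrophic programme 0 were called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.173).

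Matrix genes did not pass as a list over all arrays. Of 39 collagen and matrix genes 0 were called (1 higher, Mmp14, and 1 lower, Col15a1, adjusted over the list alone, camera adjusted p = 0.884). Col1a1 differed by log2 0.01 ± 0.33 (SE), an interval from 0.622-fold to 1.63-fold, and Col3a1 by -0.12 ± 0.19. The mean shift of the list was -0.25, 0.20 and 0.02 within batches A, B and C. By the list test it was lower in A and higher in B (camera at the preset correlation, adjusted p = 0.00108 and 0.00322). Each of these batches held 2 control and 2 diabetic animals, so this does not show that the batches responded differently. In calcium handling 0 of 19 genes were called, also over the list alone (camera adjusted p = 0.782; median -0.08 and mean 0.04). Of 23 ion channel genes 1 rose, Kcna4, a channel subunit of the transient outward potassium current (log2 1.43 ± 0.18), and 1 fell, Kcnk2 (-0.57 ± 0.13), with 1 and 2 adjusted over the list alone (camera adjusted p = 0.508). Kcnk2 lost its call for 10 of the 14 arrays left out singly (adjusted p up to 0.0932). Of 20 adrenergic and renin-angiotensin genes 0 rose and 1 fell, Adra1d (0 and 1 adjusted over the list alone, camera adjusted p = 0.933; median 0.05 and mean -0.02).

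Among 31 antioxidant genes 3 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.155). Without the 3 dimmest arrays 1 rose and 0 fell. Txnip, the thioredoxin-interacting protein that rises with glucose, was 2.44-fold higher (log2 1.29 ± 0.14, SE) and Gstm1, a glutathione transferase, rose by log2 0.67 ± 0.12. Gstp1 (0.40 ± 0.09) rose and Hmox1, heme oxygenase (-0.68 ± 0.15), fell, calls that were lost for 13 and 10 of the 14 arrays left out singly (limma adjusted p up to 0.103 and 0.0749). Of 22 endoplasmic reticulum stress genes 0 rose and 1 fell, Sdf2l1, a chaperone cofactor (-1.02 ± 0.15; 1 and 3 adjusted over the list alone, camera adjusted p = 0.103). In fatty acid and cholesterol synthesis 1 of 17 rose, the elongase Elovl6 (1.11 ± 0.23; adjusted p = 0.0540 without control replicate 3), and 1 fell, the desaturase Scd2 (-1.34 ± 0.12), with 1 and 1 adjusted over the list alone (camera adjusted p = 0.733). Probes of Scd2 can also bind related desaturase transcripts. Of 12 glycogen genes 0 rose and 1 fell, the phosphorylase kinase subunit Phkb (-0.49 ± 0.10; 1 and 2 adjusted over the list alone, camera adjusted p = 0.155), whose call was lost for 3 arrays left out singly (control replicates 1 and 7, diabetic replicate 2; adjusted p up to 0.0554). Of 19 insulin signalling genes 1 rose, Igfbp3 (0.64 ± 0.15), and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.603). Igfbp3 lost its call for 13 of the 14 arrays left out singly (adjusted p up to 0.106).

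The interferon response, macrophage and endothelial lists passed at the preset correlation and lost their calls with an estimated one and with fry (fry adjusted p = 0.0905, 0.164 and 0.0580). The interferon response list was lower, with 0 of 21 members higher and 1 lower, Usp18 (log2 -1.16 ± 0.22, SE; 0 and 6 adjusted over the list alone, camera adjusted p = 0.000133; adjusted p = 0.297 with an estimated correlation). Its shift was -0.83, -0.05 and -0.30 within batches A, B and C. The macrophage list was higher with 0 of 17 members called (1 and 0 adjusted over the list alone, camera adjusted p = 0.000599; adjusted p = 0.347 with an estimated correlation), led by Mrc1 (0.71 ± 0.18, limma adjusted p = 0.0721), and it shifted by -0.16, 0.48 and 0.47 within the batches. Of 14 endothelial genes 1 rose, the tight junction gene Cldn5 (0.94 ± 0.18), and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.0196; adjusted p = 0.267 with an estimated correlation). Within batches the endothelial shift was 0.18, 0.21 and 0.15, and the call was lost without control replicate 1, control replicate 2 or diabetic replicate 3 (adjusted p = 0.0634, 0.0578 and 0.0914).

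The atrial myocardium list was higher with 0 of 9 members called, also over the list alone (camera adjusted p = 0.0204; adjusted p = 0.189 with an estimated correlation), and shifted by 0.94, 0.79 and 0.09 within the batches. Its call was lost without control replicate 2 or diabetic replicate 7 (adjusted p = 0.0578 and 0.0513). Myl7, the atrial myosin light chain, ranged over 5.68 log2 units within the control animals and 5.03 within the diabetic animals, and the mean of Myl7, Myl4 and Sln was 9.74 ± 1.76 in control and 10.86 ± 1.73 in diabetic (SD, n = 7, exact permutation p = 0.246). The cytosolic ribosome list was higher by a mean of 0.13 with 0 of 20 genes called, also over the list alone (camera adjusted p = 0.000133; adjusted p = 0.160 with an estimated correlation; within batches 0.16, 0.12 and 0.13), and its lowest p were those of Rpl3 (0.23) and Rps23 (0.19). The cell cycle list was lower with 0 of 27 genes called, also over the list alone (camera adjusted p = 0.0104; adjusted p = 0.243 with an estimated correlation; within batches -0.28, -0.28 and -0.08), and its lowest p were those of Aurkb (-0.61) and Cdk1 (-0.58). The cell cycle call was lost in the brighter part of the probe sets (adjusted p = 0.526) and within batch C (0.458).

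**Figure D3:**
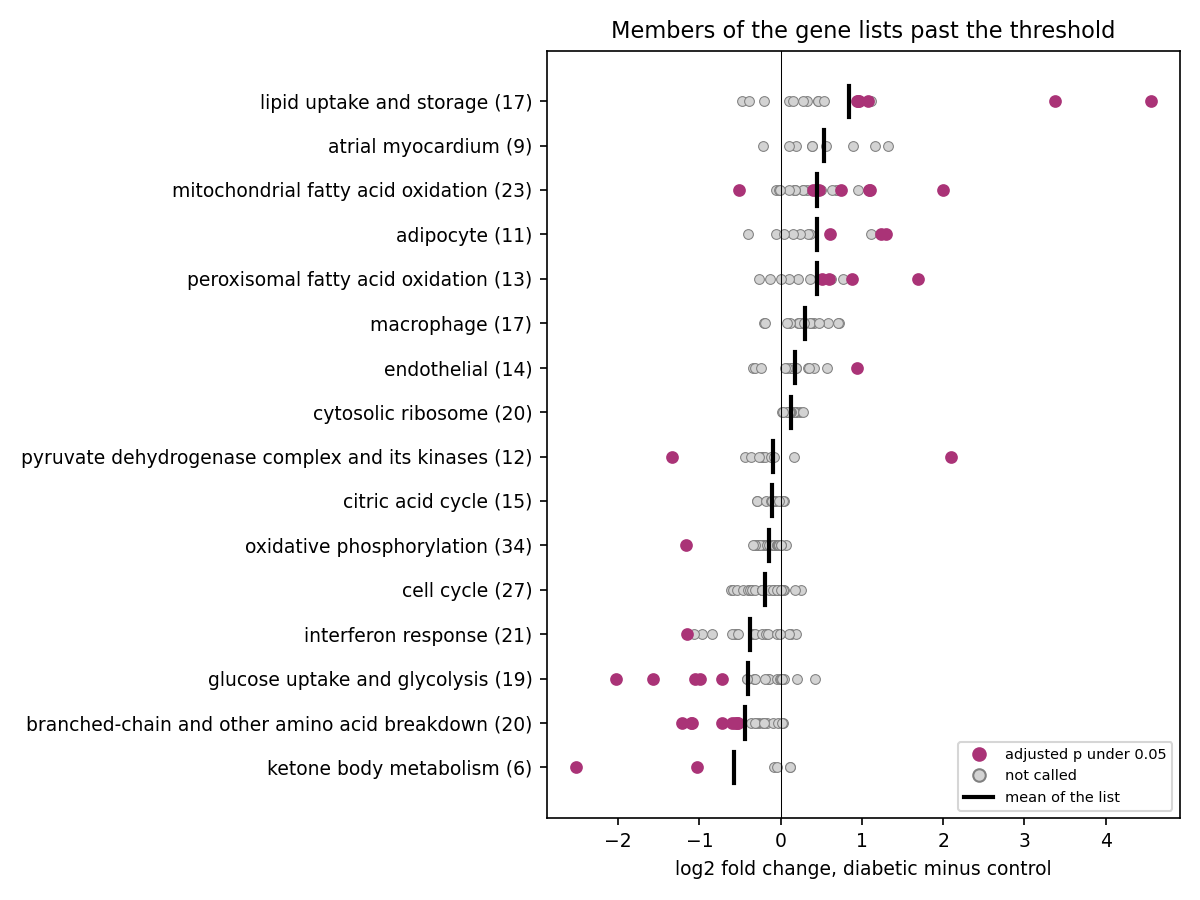
Each row is a gene list past the threshold with its number of measured genes, and each point is 1 gene at its log2 fold change, diabetic minus control; purple points passed limma's test over all probe sets and the black line is the list mean. Means ran from -0.58 for ketone body metabolism to 0.84 for lipid uptake and storage.

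In total 16 of 43 lists passed the camera test, 8 higher and 8 lower, and 5 of these held with an estimated correlation: mitochondrial and peroxisomal fatty acid oxidation, lipid uptake and storage, fat cell markers and amino acid breakdown. The lists not yet described did not pass. Erythroid and blood genes had a list test pointing up (median log2 change 0.44 and mean 0.23), with 0 of 9 called higher and 1 lower. The lower one was the anion exchanger Slc4a1 (log2 -1.22 ± 0.18, SE, with 1 and 1 adjusted over the list alone, camera adjusted p = 0.103). Thyroid and glucocorticoid responsive genes had 1 of 17 higher, Pdk4 again, and 0 lower (1 and 0 adjusted over the list alone; 0.405). The regulators of PPAR and PGC-1 had 0 of 15 called, with 0 higher and 1 lower (Lpin1) adjusted over the list alone. Camera gave that list an adjusted p of 0.914, with its direction up although the mean was -0.03. Ppara and Ppargc1a differed by 0.07 ± 0.29 and -0.03 ± 0.15. The Ppara signal (log2 6.36 in control and 6.43 in diabetic) lay near the floor set by the offset. Its small difference therefore cannot show whether Ppara changed. Neutrophil and mast cell genes had 0 of 10 called (1 higher, S100a9, and 0 lower adjusted over the list alone; 0.884). Within batch B alone the neutrophil and mast cell list passed (0.00673), as did inflammatory cytokines and adhesion (0.0274) and heat shock proteins (0.0490). For the following lists limma called 0 genes, also adjusted over the list alone, and camera gave adjusted p values of 0.0894 (heat shock proteins, 19 genes), 0.0894 (proteasome, 24), 0.0894 (cardiomyocyte, 13), 0.155 (inflammatory cytokines and adhesion, 23) and 0.207 (immediate early genes, 20). The same held for muscle atrophy and autophagy (18 genes, 0.578), smooth muscle and pericyte (14, 0.591), apoptosis (16, 0.759), circadian clock (16, 0.759) and fibroblast (15, 0.884). Lymphocyte (14) and nerve and Schwann cell genes (10) both had 0.884. Some of these lists passed under other tests set beforehand. With the trended prior camera gave adjusted p = 0.0397 (heat shock proteins), 0.0442 (proteasome) and 0.0202 (cardiomyocyte). With fry 15 lists passed, 11 of them shared with camera, and those gained were heat shock proteins (0.0445), cardiomyocyte (0.000930), antioxidant defence (0.0123) and endoplasmic reticulum stress (0.0387). Cell cycle (0.0651) and atrial myocardium (just above 0.05) were also lost with fry. With batch as a block, chosen after seeing the data, camera gave adjusted p = 0.0216 (heat shock proteins) and 0.0468 (proteasome).

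No difference in spread between the groups was resolved. The mean absolute deviation of an array from the rest of its group was 0.340 ± 0.075 log2 units in control and 0.318 ± 0.049 in diabetic (SD, n = 7). The difference of -0.022 did not pass (exact two-sided permutation p = 0.523). With single arrays left out it ran from -0.0437 (without control replicate 7) to 0.00171 (without control replicate 5), with p from 0.209 to 0.939. Control replicate 5 deviated most (0.461), followed by control replicate 6 (0.425) and diabetic replicate 5 (0.392).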

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

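The tests on batches and on the atrial markers were chosen after the values were seen; the others in this part were set beforehand. Of 154 groups of 7 values checked for a single animal far from the others, 4 stood out, where chance alone would give about 8. In control replicate 6 the mean log2 signal of the fatty acid and cholesterol synthesis list was 8.86, the lowest of its group, against 9.06 for the next animal. Control replicate 3 had the highest circadian clock list of its group (9.72 against 9.19). Diabetic replicate 2 had the lowest Gpihbp1 of its group (12.03 against 12.38), still above all controls. In control replicate 5, Col1a1 was 11.88 against 10.72 for the next control animal.

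The number of calls between the groups was weighed against technical splits of the arrays. Among 100 of the 1716 splits of the 14 arrays into 7 and 7, only the real one (1 of 100) gave 354 probe sets, and the highest other gave 4. The same held for genes (1 of 100, 245 against 2 at most) and for gene lists (1 of 100, 16 against 14 at most, with a median of 3 in the others). No other split drawn reached these counts, with a narrow margin for lists. Most of the 1716 splits were not drawn, so the test cannot give a share below 1 of 100. Probe sets called without 1 of the 3 batches had the same sign in that batch for at least 94.8%, against at most 57.8% of all probe sets. With array brightness as a covariate 92.7% of the calls stayed with the same sign. The groups were balanced over these batches, so a batch shift could not by itself separate them. The first test thus shows only that signs repeated between batches. Brightness differed little between the groups (log2 0.148, exact permutation p = 0.795), so the second test could hardly remove calls. Diabetes stays as a candidate explanation; the extraction kit per animal and other effects of streptozotocin were not tested.

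The widest spread between animals of 1 group lay in the atrial genes Myl7, Myl4 and Sln. They rose and fell together within each group: the lowest of the 6 Pearson correlations was 0.883 (Myl4 with Sln in control, Spearman 0.821; adjusted exact permutation p = 0.0140 and 0.0455, n = 7, 8 relations; 0.880 without the 2 farthest animals; 0.873 over all arrays given group and batch). This is consistent with atrial tissue in some samples, although other atrial markers did not follow in the diabetic animals (Nppa -0.499, Nr2f2 -0.138, Tbx5 -0.430, Gja5 -0.432, Pam -0.410 and Kcnj3 0.116 against the mean of the 3 genes) and followed only in part in control (0.640, 0.855, 0.425, -0.417, 0.294 and -0.038 in that order), no atrial sample was compared, and a shared regulation within the ventricle was not tested. Diabetes cannot be told apart as a further source, since the group difference of 1.12 had an exact permutation p of 0.246, nor can batch, which accounted for 23.7% of the variance. With the mean of the 3 genes as a covariate 298 of the 354 probe sets stayed called.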

How the results depend on the processing

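None of the 127 named genes reversed as a call where single genes were refitted, and over those settings 3835 values stayed on their side of the threshold, 509 lost it and 89 gained it. The main counts were 354 probe sets, 245 genes and 16 lists. Leaving out each array in turn gave 263 to 331 probe sets, 179 to 228 genes and 15 to 17 lists. Counts moved by over 1.5 times, given as probe sets and genes, to 540 and 376 with a trended robust prior, 143 and 98 with array medians subtracted, 560 and 389 in the upper part by mean signal at the median, 593 and 427 in the top quartile (fewer tests), and 174 and 117 at an adjusted p under 0.01. Among alternatives chosen after seeing the data they moved to 645 and 440 with the batch block, 561 and 391 with an offset of 200, 10 and 7 with no scaling, 189 and 125 without the 3 dimmest arrays (fewer samples), 1331 and 914 with batch block and trended prior together, and 0 and 0 within batch A, B or C (fewer samples). Only 5 lists passed with an estimated correlation. The replicate block gave 142 and 101, without the citric acid cycle list (0.0505); same-numbered arrays did not deviate together (correlations -0.161 to 0.0868), so the numbers pair nothing, and 0 of the 7 control arrays matched their own number best. The sign of the list test reversed within single batches: macrophage in A (adjusted p = 0.305), and in B interferon response (0.806, with a mean shift still at -0.05), collagens and matrix (0.00322) and fibroblast (0.00815), while the latter 2 passed as lower in A (0.00108 and 0.00116). The tests within A and B held 2 animals per group and used the preset correlation. Single arrays left out also brought in the erythroid (0.0444 without diabetic replicate 7), inflammatory (0.0476 without control replicate 2) and proteasome lists (0.0307 without control replicate 5, 0.0297 without diabetic replicate 6). Where not given, the cause was not tested. In simulated data 8.0% of probe sets changed by log2 0.5 were called, and 13.5% of the brighter ones, so changes of this size were mostly below reach.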

Other observations

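The genes in this part were chosen after their values were seen; the tests on the X chromosome were set before the neighbouring genes were looked at, while the test on the neighbours outside both families and the count of neighbouring pairs came after the values were seen. Beyond the fixed lists, single genes of amino acid breakdown were lower in diabetic animals, while other such genes were not counted: Aldh4a1, of proline breakdown (log2 -1.19, limma adjusted p = 0.000166), Hpd, of tyrosine breakdown (-1.18), and Gcsh, of the glycine cleavage system (-0.96). The apelin gene Apln was lower by 1 of its probe sets (-1.32, adjusted p = 0.000373) and not called by the other (-0.64, 0.0749). The water channel Aqp1 was lower by both of its probe sets (-1.06 and -1.08), and so was Fndc5 (-1.21 and -1.11).

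Some single genes of carbonyl and foreign compound metabolism were higher, although Dcxr, also a carbonyl reductase, was lower (log2 -1.70), and no list of such genes was tested: Cbr1 (log2 1.84, limma adjusted p = 1.34e-05), Cbr3 (1.19), Cyp2e1 (1.58), Gsta1 (1.49) and Sult1a1 (1.36). Gsta1 belongs to a family of close copies, so its own value is uncertain. Arrdc4 (1.14) and Klf10 (1.56), known to respond to glucose as Txnip does, were higher as well (adjusted p = 0.000321 and 0.000726).

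Tceal5, Bex1 and Gprasp1 (log2 2.74, 2.74 and 1.14) lie close together on the X chromosome. Over the 38 other measured genes among the 20 on either side of Tceal5, the median change was 0.09, the 98.3 percentile of 10000 random windows, which is consistent with a change shared along the chromosome, and Bex3, Tceal9, Tceal1 and Armcx4 were called higher. Cross-hybridisation between family copies may add to this, since the 6 other Bex and Tceal genes had a median of 0.55. The 32 neighbours of neither family, without Gprasp1, had a median of 0.06, at the 93.0 percentile of the same random windows. Those windows held 38 genes rather than 32, so this percentile is approximate. The 8 Armcx and Gprasp genes other than Gprasp1 had positive values with 1 called (Armcx4). Both explanations stay open, and no test here separated them.

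Across the genome, 14 pairs of neighbouring measured genes were called in the same direction, against 2.11 by chance (permutation p = 0.0001, the smallest that 10000 permutations can give). Many are pairs of related copies: Acot1 and Acot4, Acot4 and Acot3, Cbr1 and Cbr3, Tceal5 and Bex1, Bex1 and Tceal9, Tceal9 and Bex3, and Bex3 and Tceal1. The permutation moved the calls between single genes and took no account of such families, and a count without them was not made. Its p therefore cannot show that unlike neighbours change together across the genome. Pairs of unlike genes included Txnip with Ankrd34a, Ankrd34a with Lix1l, Impa2 with Cidea, and Myo5b with Acaa2. The call of Acaa2 was lost for 13 of the 14 arrays left out singly (limma adjusted p up to 0.0998).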
